A study of Mus musculus with 6 samples.

How the data were processed

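Total RNA from whole bone marrow of 6 SCID/Bg mice, 3 untreated and 3 given NOX-A12, was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 mouse per array, per the labels' protocols. Groups and mouse numbers were taken from the sample titles. The labels number separate mice, so p-values of the probe-set and exact permutation tests measure the spread between animals. Those of the gene-list test with its preset correlation rest mainly on the spread among genes. Dose, schedule, the number of animals behind the study, the hybridisation dates and the scanner were not given in the sources used here.

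The values analysed were the authors' deposited probe-set intensity values, 1 table for the whole series, already summarised per probe set. The software and normalization behind them are not given in the sources used here. The deposited intensities were linear, from 0.66 to 16790, with 781 to 861 values per array at exactly 1 and 0 to 7 below it. Array medians of log2 values lay within 0.0193 of each other, under the limit of 0.1 set for using values as deposited, so no further normalization was applied. The table held 45037 probe sets and 0 of the AFFX control type. Scanner files were not used here.

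Probe sets were named through the platform's gene annotation: 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 had none listed. Of those with 1 symbol, 34741 had a gene identifier in the reference gene table, and 0 symbols needed updating. They covered 18193 genes. No genome coordinates were used.

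Intensities were transformed to log2(intensity + 16). Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, treated against untreated, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. The moderated test had 7.24 degrees of freedom, and the median residual SD was 0.16 on the log2 scale. Replicate numbers name different animals in the groups, so no block entered the fit.

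Before the data were examined, 31 gene lists with 634 members were fixed from textbook markers of marrow cell types and pathways, of which 576 members had a probe set of their own. Camera tested 30 of them (two-sided, preset inter-gene correlation of 0.01, at least 5 measured members, Benjamini-Hochberg over the 30 lists), with the probe set of highest mean for each gene. The list of sex-linked genes was only described. The preset correlation assumes that members vary nearly independently, and its test draws its degrees of freedom from the number of genes. The same test with the correlation estimated for each list, given beside each call, draws them from the 4 residual degrees of freedom of the arrays. Mean levels of lists per mouse were compared with exact permutation tests, whose smallest two-sided p over the 10 distinct splits is 0.1.

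Named genes followed a rule also set beforehand. It took the 12 genes with the largest rise and the 12 with the largest fall past the threshold, 1 probe set per gene, with groups that do not overlap and a higher group mean above the median of all probe sets, passing over symbols of clones and predicted genes. Places left open went to the smallest unadjusted p under the other conditions, given as values that did not pass, which here was every place. Cxcl12, Cxcr4 and Ackr3 were always included, as were the 4 members with the smallest p, and any member past the threshold, of each described list. The 8 lists that the report gives only by their median have no members named under this last part of the rule.

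The scripts were tested on simulated data drawn from the means and spreads of these arrays, with 200 changed probe sets per run in 20 runs. Among calls, 3.62% were unchanged probe sets. A list shifted by 0.3 was called in 20 of 20 runs, and 0.370% of unshifted lists were called. The simulated genes were independent of each other, so this test does not bear on the choice of the preset correlation.

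Alternatives set beforehand were quantile normalization, median centring, offsets of 1 and 64, a filter on dim probe sets, a mean-variance trend with robust variances, array weights, the mouse number as a block, leaving out each mouse, other thresholds, 1 probe set per gene, other probe sets of a gene, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridising, camera with estimated correlations or on ranks, limma's fry, and list medians in place of means. Restricting lists to members that no other list holds was added after the data were seen. Panels of genes for the closing section were compared with 10000 random lists of the same size, drawn with a fixed seed from genes in the same of 20 bins of mean expression. The percentiles from this comparison rest on the spread among genes, not between animals. Figures were drawn with matplotlib from the computed values.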

Results

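Gene expression was profiled in whole bone marrow of SCID/Bg mice, an immunodeficient strain that lacks mature T and B lymphocytes and has impaired natural killer cells. Marrow came from 3 untreated mice and from 3 mice given NOX-A12, a mirror-image RNA-like aptamer that binds the chemokine CXCL12. CXCL12 is made by marrow stromal cells and retains blood-forming cells in the marrow through its receptor CXCR4. Each mouse was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, and 45037 probe sets were analysed. The dose and schedule of NOX-A12 are not given in the sources used here. Median intensity ranged from 44.8 to 45.6 over the 6 arrays, and the number of arrays limits the precision of every value. Log2 changes are NOX-A12 minus untreated on the log2(intensity + 16) scale, which understates changes of dim probe sets, and errors of changes are standard errors (SE).

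Transcripts of the drug's target and its receptors were compared first. Cxcl12 was brightly expressed in both groups. Its brightest probe set averaged an intensity of 3790 ± 268 (SD, n = 3) in untreated and 2887 ± 281 (SD, n = 3) in treated marrow, a log2 change of -0.39 ± 0.11, with all 3 treated mice below all 3 untreated mice. Its other bright probe set gave -0.49 ± 0.09, and the dimmest, near background at an intensity of 5.61 in untreated and 10.4 in treated marrow, gave 0.28 ± 0.12. Cxcr4, the receptor through which CXCL12 holds leukocytes in the marrow, differed between groups by less than its error, at 0.03 ± 0.09 (95% interval -0.19 to 0.25) and -0.03 without untreated mouse 1. Ackr3, an atypical receptor that binds and internalises CXCL12, was close to background and gave -0.29 ± 0.18. Ebf3 and Foxc1, transcription factors that maintain CXCL12-producing reticular cells, gave -0.57 ± 0.20 and -0.44 ± 0.16. Kitl, the ligand of the KIT receptor of stem cells, gave -0.41 ± 0.19, and 0.01 ± 0.23 at another probe set. None of these values passed the limma test over all probe sets (Cxcl12 adjusted p = 0.926), and 0 of the 15 measured members of the CXCL12 axis list passed when adjusted over the list alone. The list as a whole, with a median of -0.05, did not pass limma's camera test either (adjusted p = 0.0890).

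**Figure D1:**
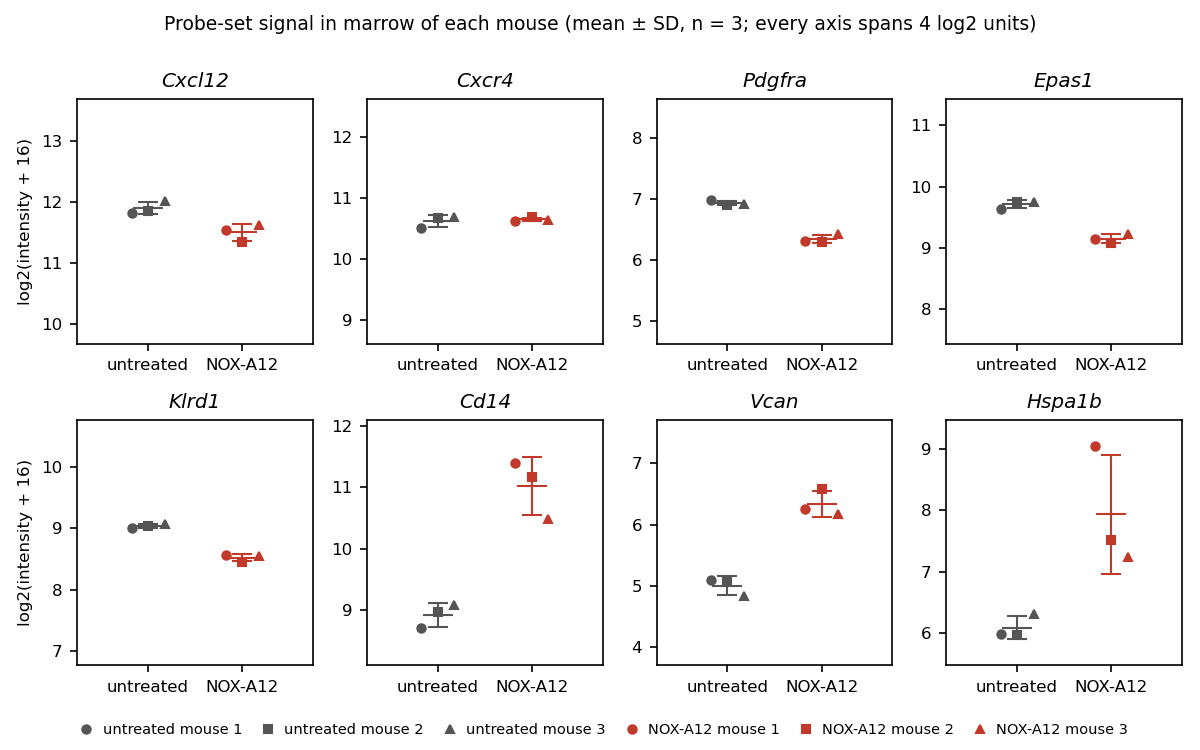
Signal of 8 genes in each mouse, as log2(intensity + 16) of the brightest probe set on the vertical axis, for untreated (grey) and NOX-A12-treated (red) mice; symbols are single mice, with the mean and SD of 3, and mouse numbers do not pair animals. Cxcl12 averaged 11.9 in untreated and 11.5 in treated marrow, Cxcr4 10.6 in both, and Cd14 8.91 and 11.02. In every panel except Cxcr4 the mice of the groups do not overlap, which was a condition for choosing all genes shown but Cxcl12 and Cxcr4.

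Across the whole array, the named genes with the smallest unadjusted p were Vcan, Cd14 and Orm1 on the higher side and Id4, Gbp6 and Klrc1 on the lower side. Cd14, the co-receptor for bacterial lipopolysaccharide on monocytes, averaged 2133 ± 648 (SD, n = 3) in treated against 468 ± 63.8 (SD, n = 3) in untreated marrow, a log2 change of 2.11 ± 0.23. Vcan, encoding the proteoglycan versican, was dim in untreated marrow and higher by 1.34 ± 0.14, although only 4 of its 7 other probe sets had the same sign. Hspa1b, an inducible heat-shock chaperone, was higher by 1.85 ± 0.43, with a wide spread among treated mice (SD 0.98). The acute-phase gene Orm1 (0.84 ± 0.11), the adenosine-producing ectoenzyme gene Nt5e (0.84 ± 0.16, but 0.03 ± 0.16 at another probe set), Mpzl2 (0.65 ± 0.09), Crispld2 (0.64 ± 0.11) and the interleukin-1 decoy receptor gene Il1r2 (0.62 ± 0.14) were also higher. So were the co-chaperone gene Dnaja1 (0.50 ± 0.12), the T-cell receptor gamma segment Trgv4 (0.49 ± 0.11), the histidine-degrading enzyme gene Hal (0.42 ± 0.09) and the myeloid membrane protein gene Ms4a6d (0.39 ± 0.10). On the lower side, Nrep gave -0.99 ± 0.17, but -0.51 ± 0.12 at another probe set. Fermt2, an activator of integrins, gave -0.83 ± 0.14 (0.15 ± 0.11 at a dimmer probe set), and the transcription factor gene Snai2 -0.76 ± 0.12. Plpp3 gave -0.69 ± 0.12, and the transcriptional regulator gene Id4 gave -0.67 ± 0.09. The interferon-inducible genes Gbp6 and Epsti1 gave -0.67 ± 0.09 and -0.58 ± 0.10. Klrc1 and Klrd1, whose products pair as a receptor on natural killer cells, gave -0.60 ± 0.09 and -0.52 ± 0.09. Pdgfra, a receptor of mesenchymal stromal cells, gave -0.58 ± 0.09, the hypoxia-regulated transcription factor gene Epas1 -0.56 ± 0.09, and Adgrf5 -0.53 ± 0.09.

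None of these single genes passed the test. With limma and Benjamini-Hochberg adjustment, 0 probe sets were higher and 0 were lower at an adjusted p under 0.05, and the lowest adjusted p was 0.790. At an unadjusted p under 0.05 there were 845 higher and 1395 lower probe sets, 2240 in all against 2252 expected by chance. That count depended on single mice: it was 3555 without untreated mouse 1, where the lowest limma adjusted p was 0.0631, and 1508 without NOX-A12 mouse 1. The lowest adjusted p was 0.216 without NOX-A12 mouse 3, and 0 probe sets passed without any of the 6. The groups did not overlap for 4437 probe sets, or 9.85%, where chance gives 10%. In simulated data with the spread of these arrays, the same test called 17.2% of 1.5-fold, 65.5% of 2-fold and 91.7% of 4-fold changes among probe sets above the median intensity. The genes in the preceding paragraph are therefore values that did not pass, chosen by their unadjusted p.

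Genes of the marrow's stromal and vascular niche were lower as groups in treated mice. Of 22 stromal reticular genes, 21 were lower, with a median log2 change of -0.41. Igfbp5, which encodes a binding protein of insulin-like growth factors, gave -0.61 ± 0.11, the collagen gene Col3a1 -0.40 ± 0.08, and Esm1 -0.93 ± 0.24. Of 22 endothelial genes, 20 were lower, with a median of -0.19. Robo4, a guidance receptor of endothelium, gave -0.62 ± 0.12, and the vascular growth factor receptor genes Kdr and Flt4 gave -0.54 ± 0.12 and -0.43 ± 0.11. Cldn5, a tight-junction protein gene, gave -0.58 ± 0.15. Of 11 adipocyte genes, 8 were lower, with a median of -0.37, among them Pparg, the regulator of fat-cell differentiation (-0.58 ± 0.12), Adipoq, which encodes adiponectin (-0.56 ± 0.21), the fatty-acid carrier gene Fabp4 (-0.52 ± 0.21) and the carbonic anhydrase gene Car3 (-0.49 ± 0.16). Of 24 extracellular matrix genes, 19 were lower, with a median of -0.23, including the basement membrane gene Nid1 (-0.67 ± 0.14), the collagen cross-linking enzyme gene Lox (-0.47 ± 0.14) and Dcn (-0.47 ± 0.14), one of whose dimmer probe sets gave 0.29.

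The 4 niche lists passed camera's test with its preset correlation between genes, at an adjusted p of 3.22e-12 for stromal reticular, 1.81e-07 for endothelial, 9.66e-04 for adipocyte and 1.83e-05 for extracellular matrix genes. None passed with a correlation estimated from these arrays: adjusted p = 0.217, 0.215, 0.299 and 0.299 with an estimated correlation, in the same order. In the limma fit 0 members passed over all probe sets, while adjusted over the list alone 7 stromal, 8 endothelial, 1 adipocyte and 2 extracellular matrix genes passed as lower. The mean level of the list did not overlap between groups for stromal, endothelial and extracellular matrix genes (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 mice can give). Untreated mouse 3, whose array stood apart as described below, had the highest level of the stromal (0.38 above the mean of the 6 mice), endothelial (0.21), adipocyte (0.27) and extracellular matrix lists (0.18), and also of the skeletal muscle list (0.26). The stromal list shared 5 members with the CXCL12 axis list, 3 with the matrix list and 2 with the adipocyte list. The osteoblast and bone matrix list was lower by a median of -0.16 over 14 genes, among them the matrix gene Postn (-0.53 ± 0.19), Phex (-0.52 ± 0.18), the alkaline phosphatase gene Alpl (-0.39 ± 0.14) and the bone glycoprotein gene Sparc (-0.34 ± 0.17). Its camera adjusted p was 0.0447, and adjusted p = 0.575 with an estimated correlation. That call, with 10 of 14 genes lower, was lost in camera without untreated mouse 2 (adjusted p 0.351), untreated mouse 3 (0.115) or NOX-A12 mouse 2 (median -0.03, 0.581), and in 6 of 12 other settings, quantile normalization among them; the median was -0.25 without NOX-A12 mouse 3. The adipocyte median was -0.20 without NOX-A12 mouse 2 and the extracellular matrix median -0.36 without untreated mouse 1, with both calls kept.

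**Figure D2:**
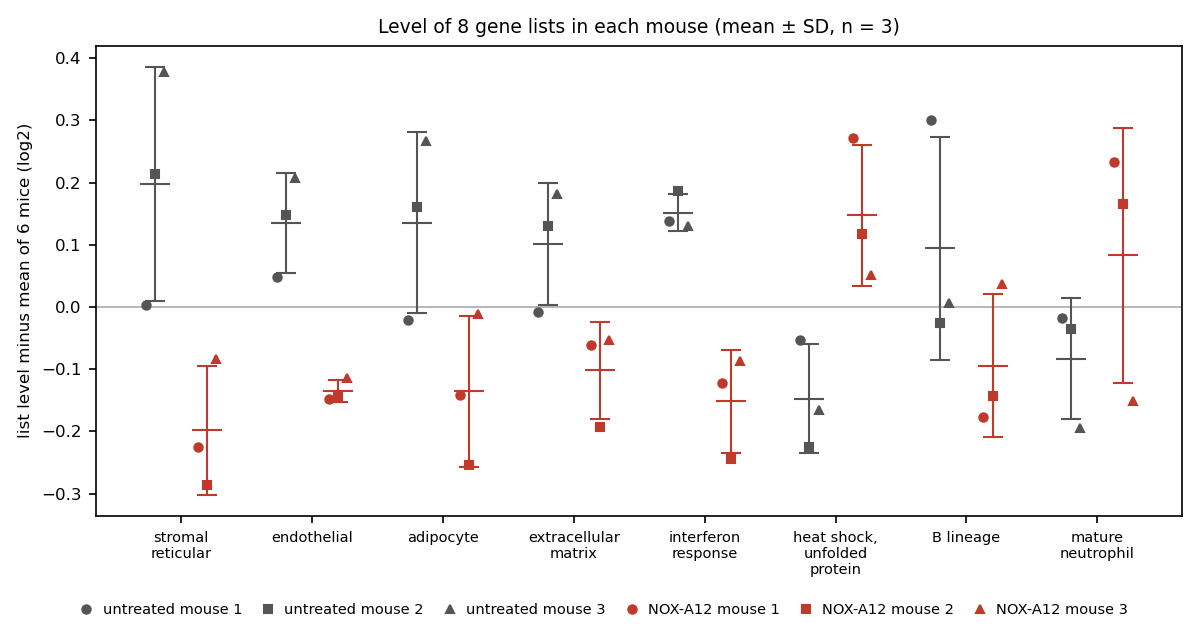
Level of 8 gene lists in each mouse, as the mean log2 value over the list's members minus the mean of the 6 mice on the vertical axis, for untreated (grey) and NOX-A12-treated (red) mice; symbols are single mice, with the mean and SD of 3. The groups do not overlap for the stromal, endothelial, matrix, interferon and heat-shock lists and overlap for the adipocyte, B lineage and mature neutrophil lists.

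Interferon-inducible genes were lower as a group in treated marrow. Of 26 measured genes, 24 were lower, with a median of -0.27, and 14 of them had an unadjusted p under 0.05. Irf7, a transcription factor that amplifies the interferon response, gave -0.44 ± 0.10, the antiviral effector gene Ifit3 -0.43 ± 0.10, and the interferon-inducible GTPase genes Gbp2 and Iigp1 -0.43 ± 0.09 and -0.49 ± 0.12. Adjusted over the list alone, 6 genes passed as lower, and 0 passed over all probe sets. The list's camera adjusted p was 1.08e-11, and adjusted p = 0.215 with an estimated correlation. The list level was lower in every treated mouse than in every untreated mouse (exact permutation p = 0.1, two-sided).

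Immune-cell lists were lower by smaller amounts. In the dendritic list, 12 of 19 genes were lower. The antigen-presentation genes H2-Eb1, H2-Aa and H2-Ab1 gave -0.40 ± 0.10, -0.37 ± 0.10 and -0.31 ± 0.09, and the chemokine receptor gene Ccr9 gave -0.39 ± 0.11, but 0.05 and 0.23 at its dimmer probe sets. In the B lineage list, 16 of 20 genes were lower, among them Cd74, the chaperone of class II molecules (-0.41 ± 0.09), the antigen-receptor component gene Cd79a (-0.53 ± 0.15), Igll1, which encodes part of the pre-B-cell receptor (-0.57 ± 0.16), and the B-cell scaffold gene Bank1 (-0.36 ± 0.10). In the T and natural killer list, 12 of 18 genes were lower. Eomes, a transcription factor of natural killer cells, gave -0.37 ± 0.11 and the chemokine gene Ccl5 -0.38 ± 0.12, while the T-cell receptor complex gene Cd3d gave 0.46 ± 0.14. Some T-cell genes counted as lower, such as Cd3e and Cd4, were near background, at intensities of 9.63 and 3.98 in untreated marrow. The monocyte and macrophage list, with 17 of 22 genes lower, held members that went opposite ways: Siglec1, Mertk and Mrc1, surface receptors of tissue macrophages, gave -0.48 ± 0.12, -0.45 ± 0.13 and -0.32 ± 0.10, while Cd14 was the member with the largest difference and was higher. At an unadjusted limma p under 0.05, 2 members of this list were higher, Cd14 among them, and 4 were lower. Its mean change was only -0.04. The medians were -0.17 for the dendritic, -0.17 for the B lineage, -0.11 for the T and natural killer and -0.18 for the monocyte and macrophage list.

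Camera's adjusted p was 0.0125 for the dendritic, 5.43e-04 for the B lineage, 0.0249 for the T and natural killer and 0.0186 for the monocyte and macrophage list. None of these passed with an estimated correlation, a test that called 0 lists in any split of the mice: adjusted p = 0.217, 0.473, 0.467 and 0.467, in the same order. The mean level of the dendritic list did not overlap between groups (exact permutation p = 0.1, two-sided), while those of the other lists overlapped. Adjusted over the list alone, 5 dendritic genes, 1 B lineage gene (Cd74) and 1 T and natural killer gene (Klrd1) passed as lower, and 1 monocyte and macrophage gene (Cd14) passed as higher. Over all probe sets 0 passed. Without untreated mouse 1 the dendritic (median -0.04), B lineage (median -0.11) and T and natural killer calls were lost, at a camera adjusted p of 0.1004, 0.218 and 0.218. Without untreated mouse 2 the dendritic (median -0.09), T and natural killer and monocyte (median -0.10) calls were lost, at 0.0819, 0.0552 and 0.171. Without NOX-A12 mouse 3 they were lost at 0.0791, 0.233 and 0.237, the dendritic median then being -0.09. Larger B lineage medians came without untreated mouse 2 (-0.28) or 3 (-0.32), and the T and natural killer median was -0.21 without NOX-A12 mouse 1 and -0.18 without untreated mouse 3. Without NOX-A12 mouse 1 the dendritic median was -0.09. Camera on ranks ended the dendritic and the T and natural killer calls, and averaging all probe sets of a gene ended the monocyte call.

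Chaperone genes were higher in treated marrow. All 21 measured members of the heat shock and unfolded protein list were higher, with a median of 0.16. Hsph1, which encodes a large heat-shock protein, was higher by 1.06 ± 0.29, next to Hspa1b, and the constitutive chaperone gene Hspa8 by 0.27 ± 0.10. Creld2, a gene induced by stress of the endoplasmic reticulum, was higher by 0.32 ± 0.12. The list's camera adjusted p was 5.19e-08, and adjusted p = 0.217 with an estimated correlation. The list level was higher in every treated mouse than in every untreated mouse, and 0 members passed either over all probe sets or when adjusted over the list alone.

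Primary granule, mature neutrophil, immediate early and adhesion genes were higher by amounts that depended on single mice. All 11 measured members of the primary granule list were higher, with a median of 0.12. They included the histidine decarboxylase gene Hdc (0.37 ± 0.11), which the mast cell, basophil and eosinophil list also holds, and Cst7 (0.25 ± 0.10). The chaperone gene Calr gave 0.20 ± 0.11 and the myeloperoxidase gene Mpo 0.12 ± 0.10. Of 17 mature neutrophil genes, 12 were higher, with a median of 0.10. The lectin receptor genes Clec4d and Clec4e gave 0.48 ± 0.16 and 0.41 ± 0.15, the cytokine gene Il1b gave 0.38 ± 0.20, and Il1r2 alone passed when adjusted over the list alone. Of 20 immediate early genes, 16 were higher, with a median of 0.25, such as Ier3 (0.35 ± 0.12) and Nr4a1 (0.30 ± 0.11). Fosb (0.45 ± 0.17) and Egr2 (-0.32 ± 0.10) were both dim on these arrays. Of 29 adhesion and migration genes, 21 were higher, with a median of 0.07, among them the integrin gene Itga5 (0.25 ± 0.10, at a dim probe set), the collagenase gene Mmp8 (0.12 ± 0.09), and the GTPase genes Rhoa (0.13 ± 0.12) and Rac2 (0.30 ± 0.28), the last of which changed sign without untreated mouse 3 (-0.05) and at another probe set (-0.18).

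Camera's adjusted p was 0.00118 for primary granule, 0.0147 for mature neutrophil, 0.00239 for immediate early and 0.0275 for adhesion and migration genes, and adjusted p = 0.467, 0.473, 0.473 and 0.575 with an estimated correlation, in the same order. All 4 calls were lost without untreated mouse 3, at an adjusted p of 0.152 (median 0.03), 0.183 (median 0.00), 0.139 (median 0.15) and 0.953 (median 0.01). The array of this mouse stood apart from the other 5: it correlated with them at r from 0.982 to 0.985 across probe sets, which are not independent replicates, against 0.991 to 0.994 among the other arrays. On it 851 probe sets lay over 2-fold from the median of the other arrays, against 44 to 67 on each of the others. The mature neutrophil call was also lost without NOX-A12 mouse 1 (median 0.00, 0.0952) or NOX-A12 mouse 2 (median 0.03, 0.109), and its median was 0.22 without NOX-A12 mouse 3 and 0.06 without untreated mouse 1. The immediate early call was also lost without NOX-A12 mouse 1 (median 0.15, 0.122), and the adhesion call without NOX-A12 mouse 2 (0.156). The primary granule median was 0.19 without untreated mouse 2, and the adhesion median 0.11 without untreated mouse 1 or 2. Camera on ranks ended the mature neutrophil call, and array weights, the mean of all probe sets of a gene or leaving out cross-hybridising probe sets ended the adhesion call. Both were also lost over members that no other list holds, a setting chosen after the data were seen.

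Blood-forming lineages outside these groups did not pass with either correlation. Erythroid genes had a median of 0.03 over 23 genes, with -0.21 ± 0.15 for the globin gene Hba-a1, whose probe set was near background at an intensity of 13.02 in untreated marrow, 0.14 ± 0.11 for the mitochondrial iron importer gene Slc25a37, -0.10 ± 0.10 for Gata1, the master regulator of red-cell genes, and -0.09 ± 0.10 for Car1. Secondary and tertiary granule genes had a median of 0.04, with 0.12 ± 0.09 for Chil3, 0.12 ± 0.09 for Mmp8, 0.12 ± 0.13 for the gelatinase gene Mmp9 and 0.17 ± 0.14 for Cd177, a neutrophil surface protein gene. Megakaryocyte and platelet genes had a median of -0.08, with -0.30 ± 0.16 for the adhesion receptor gene Selp, -0.26 ± 0.22 for the platelet tubulin gene Tubb1, -0.20 ± 0.17 for Vwf and -0.22 ± 0.22 for the integrin gene Itga2b. Stem and progenitor genes had a median of -0.05, with 0.58 ± 0.21 for Spink2, 0.18 ± 0.11 for the cytokine receptor gene Flt3, and -0.18 ± 0.10 and -0.24 ± 0.14 for the transcription factor genes Hoxa9 and Mecom. Proliferation genes had a median of 0.02 over 29 genes, with -0.15 ± 0.10 and -0.10 ± 0.10 for the replication helicase genes Mcm7 and Mcm3, -0.18 ± 0.13 for the cyclin gene Ccne1 and 0.29 ± 0.28 for Tyms, which gave -0.05 without untreated mouse 3. Other probe sets above the median intensity had the opposite sign for Selp (0.04), Hoxa9 (0.17), Mcm7 (0.05), Mcm3 (0.18) and Tyms (-0.01). Skeletal muscle genes had a median of -0.03, with -0.24 ± 0.10 for the enolase gene Eno3, -0.14 ± 0.10 for the troponin gene Tnni2 and 0.38 ± 0.14 for the creatine kinase gene Ckm, at a dim probe set. The myosin gene Myh1 gave -1.24 ± 0.91, and -0.06 ± 0.27 without untreated mouse 3. Among the others, the medians were -0.01 for mast cell, basophil and eosinophil genes, -0.01 for osteoclast genes, 0.04 for inflammatory response genes and 0.02 for hypoxia and glycolysis genes. They were 0.04 for p53 and apoptosis genes, -0.02 for iron and heme genes, -0.03 for oxidative phosphorylation genes and 0.00 for ribosomal protein genes. Over the lists of this paragraph the camera adjusted p ranged from 0.232 to 0.894. For the stem and progenitor, the mast cell, the hypoxia, the p53 and the ribosomal lists, the median, the mean and the direction of the test did not all have the same sign.

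**Figure D3:**
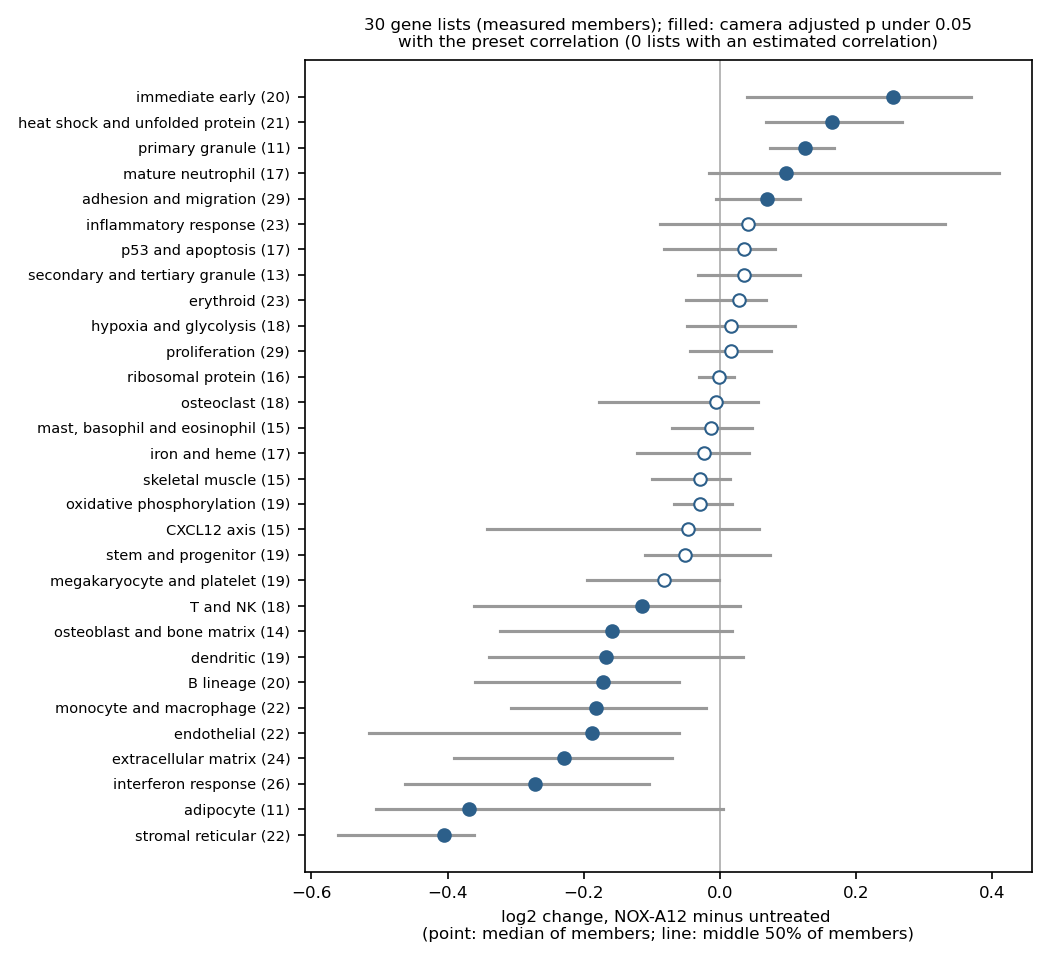
Median log2 change of the measured members (horizontal axis, NOX-A12 minus untreated) of the 30 tested gene lists, with a line over the middle part of the members' values and the number of members in brackets; filled points passed camera's test with its preset correlation. The stromal reticular list lies lowest at -0.41 and the immediate early list highest at 0.25, and 0 lists passed with an estimated correlation.

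In all, camera with its preset correlation called 5 of 30 lists higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p = 0.215). The levels of 6 lists did not overlap between groups, where chance gives 3.1. They were the stromal reticular, endothelial, extracellular matrix, interferon, heat shock and dendritic lists. Some of these share members, so the chance count does not measure how unusual 6 is. A partly different set of 6 kept its preset-correlation calls under every mouse left out. It held the stromal reticular, endothelial, adipocyte, interferon, heat shock and extracellular matrix lists. The sex-linked genes, given as a check of the animals, showed Xist between 12.4 and 12.6 on the log2 scale in all 6 mice at its brightest probe set, and the Y-linked genes Kdm5d, Uty and Eif2s3y near background in all.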

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

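The setting restricted to members that no other list holds was chosen after the data were seen. For single probe sets, 0 were higher and 0 lower in limma under every normalization, offset, filter, variance model and left-out mouse; at an unadjusted p under 0.05 with at least 1.5-fold, 54 were higher and 96 lower. With the mouse number as a replicate block there were again 0 and 0 probe sets, and 5 higher and 10 lower lists; same-numbered mice did not deviate together (r of -0.09, 0.05 and 0.03). For lists, the 5 higher and 10 lower calls of camera's preset correlation became 0 and 0 with an estimated correlation. Limma's fry gave 0 higher and 1 lower list (endothelial) for its directional test, while 8 lists passed its mixed test, which has no direction, against 15 in camera. Over members that no other list holds, 3 lists were higher. The cause of these differences was not tested, except that camera with an estimated correlation works with the 4 residual degrees of freedom, by construction. Estimated correlations also differed from the preset 0.01. They were 0.27 for the stromal reticular, 0.36 for the B lineage, 0.39 for the primary granule and 0.16 for the heat-shock list. For the dendritic list the estimate was -0.004, so a higher correlation is not why that call was lost. Leaving out 1 mouse gave 1 to 7 higher and 6 to 10 lower lists; the 1 higher list came without untreated mouse 3 and the 6 lower lists without untreated mouse 2, with 3 higher without NOX-A12 mouse 1 or 2. The adhesion list's median then ranged from 0.011 to 0.11, and the test's direction reversed without untreated mouse 3. Cxcl12 gave 0.28 and Dcn 0.29 at another probe set, each the reverse of the brighter one, and the cause was not tested. A gene was counted as reversed only if it had been called or both values exceeded 2 SE, a rule set after a first look; in plain signs, 7 of 1958 gene values, 41 of 155 values from other probe sets and 28 of 217 list levels changed sign, and 11 list levels moved by over 1 SD. Signals near background, with 781 to 861 values per array at exactly 1, limit what dim probe sets show.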

Other observations

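Tests chosen only after the result they measure was seen were those of the intensity trend, of untreated mouse 3, of bone-adherent tissue, of the interferon genes against both macrophage panels and of handling time; the counts over splits of the mice and the added gene panels were set before their values were seen. The added panels, of further macrophage, heat-shock factor, glucocorticoid and monocyte genes, hold genes outside the fixed lists. The 13 macrophage genes set against the interferon list below are not among them, since they came from a fixed list. In a second panel of resident macrophage genes, 8 of 10 were lower in treated marrow, with a median log2 change of -0.31. Folr2 and Marco, counted as lower, were near background, at a mean log2 value of 4.66 and 4.56. Igf1, which macrophages and stromal cells both make, gave -0.62 ± 0.17 (SE), the complement receptor gene Vsig4 -0.32 ± 0.11 and the prostaglandin-degrading enzyme gene Hpgd -0.35 ± 0.13, while the lectin receptor gene Clec4n gave 0.94 ± 0.31. Among 12 further targets of heat-shock factor, 8 were higher, with a median of 0.15, led by the chaperone partner gene Chordc1 (0.43 ± 0.14), Hspa4l (0.31 ± 0.13) and Cacybp (0.29 ± 0.11). Cirbp, a cold-inducible RNA-binding protein gene chosen after its value was seen, gave -1.02 ± 0.21. None of these genes passed limma's test over all probe sets.

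Splits of the 6 mice were too few for a share under 0.05. For probe sets the count tests nothing: the real split gave 0, which all 10 reach by construction, and the highest other gave 2. For lists, 2 of the 10 gave 15 camera calls, the real split with 15 and another with 15, which set untreated mouse 1 and NOX-A12 mice 1 and 2 against the rest. That split also had 3769 probe sets at an unadjusted p under 0.05, against 2240 in the real one, and why was not tested. Further splits with more than the real one had 2800 and 2452. Single lists were looked up in the splits only after their calls were seen. The stromal list was also called by camera's preset correlation in 4 of the 9 other splits, the interferon and heat-shock lists in 3 each and the endothelial list in 2, with 0 lists called in any split with an estimated correlation.

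Stromal reticular and endothelial lists were called lower by camera with its preset correlation, with adjusted p = 0.217 and 0.215 with an estimated correlation. An intensity-dependent trend left by the normalization is argued against, since both medians lay at percentile 0 of 10000 random lists matched on mean expression (middle 95% from -0.07 to 0.05 for the stromal and from -0.10 to 0.05 for the endothelial list). Untreated mouse 3, which stood apart and had the highest stromal, endothelial and muscle levels, does not account for it alone, since without it 75.4% of the stromal median remained, the smaller share of both lists, and both kept their preset-correlation call. Less bone-adherent tissue in the harvest cannot be told apart from a change in stromal transcription: stromal minus osteoblast level differed by -0.23, with a 95% interval of -0.51 to 0.04. An effect of NOX-A12 on the cells that make its target may therefore be one candidate explanation and uneven recovery of stroma another.

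The interferon list was called lower with the preset correlation, with adjusted p = 0.215 with an estimated correlation. The intensity trend is argued against here too, with the median at percentile 0 of matched random lists (middle 95% from -0.07 to 0.05). Fewer resident macrophages, which express many of these genes, may account for it. A comparison with 13 macrophage genes (median -0.30, difference -0.016) decides nothing, because they were picked after values were seen from 22 members with a median of -0.18, leaving out genes such as Adgre1 (-0.04), Mpeg1 (-0.05) and Cd68 (0.03). Against the second panel the interferon level differed by -0.11, with a 95% interval of -0.47 to 0.25, so both fewer macrophages and a lower interferon tone stay open.

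The heat-shock list was called higher with the preset correlation, with adjusted p = 0.217 with an estimated correlation. Warmer animals or tissue could produce this: the 12 further heat-shock factor targets lay at percentile 99.99 of matched random lists, but their level overlapped between the groups, so the question stays open. The gene Rbm3, named in advance as a cold-inducible readout, had probe sets listed for several genes and was not analysed here. Longer handling of the cells also stays open, since the immediate early level differed by 0.20, with a 95% interval of -0.39 to 0.80 that includes the difference in the heat-shock level (0.29).

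Hypotheses on cell composition and on a hormonal response were tested as biological explanations, and none was settled. For Cd14 and Vcan higher beside macrophage receptors lower, a loss of resident macrophages had its second panel at percentile 0 of matched random lists, although panel levels overlapped between groups (95% interval of the difference -0.49 to 0.10). Such percentiles rest on the spread among genes, not between animals. A gain of classical monocytes had its panel of 10 genes at percentile 94.27, with a median of 0.06 and an interval of -0.13 to 0.32. A glucocorticoid response, which could join Il1r2, Orm1 and Crispld2 higher with B lineage and interferon genes lower, had its 10 induced genes at percentile 89, with a median of 0.05. Their level differed by 0.03 with an interval of -0.60 to 0.67, and 6 were higher and 4 lower, with 0.39 ± 0.22 for Fkbp5 and -0.13 ± 0.75 for Per1. The monocyte and glucocorticoid medians met the bound set in advance against those explanations. That bound was too loose, because members went both ways and the intervals are wide, so neither is excluded. The rises of Cd14 (2.11) and Vcan (1.34) lie outside the interval of the 10 monocyte genes, but this decides nothing. That interval is for a mean over genes such as Plac8 and Lgals3, already bright in whole marrow (mean log2 of 12.8 and 12.4). Such genes need not rise as much as Cd14 and Vcan, which were chosen by their unadjusted p. A gain of monocytes therefore stays open.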
